A study of Homo sapiens with 31 samples.

How the data were processed

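RNA sequencing covered 31 samples in 11 groups. A set of 27 libraries came from TMD8, RIVA and HBL1, established cell lines of activated B-cell-like diffuse large B-cell lymphoma, a lymphoma type that often relies on B-cell receptor (BCR) signalling. Each line received DMSO (the solvent control), 10 nM ibrutinib (an inhibitor of the BCR kinase BTK) or 60 µM Rhosin (an inhibitor of RHOA) for 10 h, with 3 replicates per line and treatment. The other 4 libraries came from TMD8 cells with wild-type RHOA (WT) or with the p.R5W change knocked into RHOA (R5W), 2 each, kept overnight in 50 nM copanlisib, a PI3K inhibitor. Per the labels' protocols, the 2 sets were made at different facilities with different stranded kits, so fold changes were computed within each set, and levels of the 2 sets were compared only to check which gene a row of the drug tables holds.

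Per the submitters' processing notes, bcl2fastq, cutadapt, STAR, RSEM and Picard were used with the builds GRCh37 and hg19. Their versions, and which tool and build served which set, are not given in the sources used here. For the drug set the authors deposited raw counts, 1 table per line, each with 63140 Ensembl gene IDs and no symbols. Totals ran from 8911238 to 14153796 counts per library. The 13 rows whose IDs name mitochondrial protein-coding genes took 20.5% to 27.8% of them. The check of labels described below left out the mitochondrial chromosome, so the genes behind these rows are unchecked. For the R5W set the authors deposited log2 values for 25073 gene symbols, of which 27 had been turned into dates and were restored. With the logarithm undone and each library divided by the value of 1 read, 100% of the values up to 200 reads were whole numbers within 0.1 read, so each value was the log2 of a count times a factor per library. The reads recovered in this way came to 19459885 to 21955743 per library. These depths bound counting error only, since the reads carried no molecular identifiers. The plan had foreseen counts or normalized values for each table; because this table held log2 values of scaled counts, they were taken back to the linear scale and given the test planned for normalized values.

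Symbols were found for 62541 of the drug tables' IDs and not for 599, and positions for 58126 IDs in GENCODE v29, which is on GRCh38. An annotation of GRCh37 was not used here, and no coordinate was converted between builds. The counts under most IDs did not follow the levels of the genes that the IDs name. Across 14858 genes matched to the log2 table, Spearman's rho between the mean counts of the TMD8 DMSO libraries and the mean log2 values of the WT libraries was 0.106. Among well known genes, IRF4 held a mean of 71858 counts in TMD8 DMSO, while GAPDH, MYC and TUBA1B held 0. Genes of the drug tables were therefore named only inside 8 segments. In these a running rho over 21 neighbouring genes stayed over 0.7 for at least 30 consecutive genes. A level check also required that count and level lay within 2 log2 units of the trend between them, or that both were low. It used the TMD8 DMSO counts and was not repeated in RIVA or HBL1, where names rest on the same IDs. The levels came from WT cells under copanlisib, so genes that copanlisib moves strongly could fail the check. The segments, in GRCh38, were chromosome 11 from 167784 to 1262172, 18 from 158383 to 12658134, 19 from 60951 to 6857366, 4 from 1166932 to 38782990 and from 38823715 to 48040173, 5 from 92151 to 41261438, 6 from 291630 to 27256624 and 9 from 116231 to 39288315. They held 3020 table rows (4.78% of rows and 20.18% of the TMD8 DMSO counts), and rho was 0.907 over 683 matched genes inside them against 0.07 over 14175 outside. In RIVA rho was 0.851 inside and 0.088 outside, and in HBL1 0.835 and 0.08. With levels shifted circularly along the genome 100 times, the longest run over 0.7 held 12 genes, and outside the segments the longest held 16. The level check removed 105 matched genes and left 700 label-checked genes. Among the 700 are genes at 0 in both TMD8 DMSO and WT, which offer no signal to check and were left out of rho. The segments and the level check were chosen after the data were seen. In the scan of 10 Mb blocks, 16 overlapped a segment. In 15 of them the counts followed the genes best at a shift from -2000 to 1100 bp, which was 0 in 2 blocks, so part of a gene's exons can be missing from its counts in the segments. In the first block of chromosome 11, whose segment covers only its start, the best shift was -21400 bp. All other rows were tested and are reported as table rows, without names, because which gene their reads came from is unknown.

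Each line's 9 libraries were fitted in 1 model with a mean per treatment (edgeR 4.0.16, filterByExpr, TMM scaling, quasi-likelihood F test). Interactions between line and treatment were tested in 1 model of all 27 libraries. R5W was compared with WT by limma 3.58.1 (trend, robust) on log2 of the value plus 1, for genes at 10 or more in at least 2 libraries. All p-values were two-sided and adjusted by Benjamini and Hochberg over the rows or genes tested, with a threshold of 0.05. Fold changes are log2 with their standard error (SE), levels in the drug set are counts scaled to library size (CPM) with their SD, and n is 3 per group in the drug set and 2 in the R5W set. For label-checked genes the adjustment is that over all rows tested. The 24 gene lists were tested with camera at a preset correlation of 0.01, and again with the correlation estimated from the libraries, where at least 3 members were measured. In the drug tables this was so for 1 list, so its camera p there is unadjusted, also over the 9 drug comparisons. With an estimated correlation camera takes its degrees of freedom from the libraries and not from the genes. This alone weakens a test of 4 libraries. Genes named are RHOA; the 6 that rose most and the 6 that fell most in each comparison with DMSO and in R5W against WT, among those past the threshold with at least 10 CPM and no overlap between the groups' replicates; the 5 with the smallest adjusted p for Rhosin against ibrutinib and for the interactions; and up to 4 members of a gene list with the smallest adjusted p, plus its best known member. Names of clones, pseudogenes and the like were passed over, and, decided after the results were seen, 8 genes and 1 list in R5W against WT are not reported here; the sensitivity counts include them, among them the 1 gene whose direction reversed when a replicate was left out. Groups, tests, lists, the rule for naming genes and the alternatives were set before the data were examined, except where a later choice is stated.

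Replicate numbers were taken to pair libraries where the deviations from the group means correlated over 0.1 in every same-numbered pair. In HBL1 they did in all 3 comparisons, with correlations from 0.29 to 0.68. Libraries numbered 1 and 3 of different treatments correlated there too, at 0.23 to 0.3. In TMD8 they did for Rhosin against DMSO (0.12 to 0.17) and Rhosin against ibrutinib (0.12 to 0.25) and not for ibrutinib against DMSO (lowest 0). In RIVA they did not in any comparison (lowest -0.11). Most same-numbered RIVA pairs still correlated above 0, up to 0.39, beside -0.37 to 0.21 for different numbers. Missing the rule therefore does not exclude a replicate effect in RIVA. The labels state no pairing, so it comes from the data alone. A second fit held the replicate number as a block, and the HBL1 genes were named by the same rule from that fit, with the same direction in all 3 pairs in place of no overlap, a choice made after the data were seen. No source used here states whether replicates came from separate cultures, so the p-values measure the spread between these samples. Replicates of 1 group differed by more than counting noise in all 29 pairs (chi-square per degree of freedom 3.52 to 35.81).

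The tests were run on simulated counts with 200 genes changed by 1.5, 2 or 4-fold. At these folds the TMD8 Rhosin simulation (10633 rows) recovered 49.3%, 64.2% and 92.4%, the RIVA Rhosin simulation (11597 rows) 22.4%, 61.2% and 90.9%, and the HBL1 Rhosin simulation (11421 rows) 3%, 31.3% and 72.7%. With replicate effects added to the HBL1 simulation (11430 rows), 7.5%, 35.8% and 71.2% were recovered without the block and 52.2%, 64.2% and 87.9% with it. For the Rhosin effect between lines (13615 rows) the shares were 7.5%, 23.9% and 69.7%, and for R5W against WT (13294 genes) 68.7%, 80.6% and 98.5%. False calls were 12.2% of calls in the R5W simulation (23 calls) and 7.5% in the HBL1 simulation with the block (11 calls), against the 5% that the threshold aims at. They were 5.5% for TMD8, 5.7% for RIVA, 5.3% for HBL1, 0% for HBL1 with replicate effects and no block, and 1.5% between lines. A planted list of 25 genes raised 1.5-fold was called by camera (adjusted p = 9.9e-26) and 0 of 20 unchanged lists were. Genes were drawn independently there, so this does not measure false calls for real lists, whose genes can vary together.

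Alternatives comprised DESeq2 1.42.0, RLE size factors, no low-count filter and a stricter one of 1 CPM, the replicate block, the compared libraries alone, a log2 fold limit of 1, each replicate left out in turn and, for R5W, quantile normalization, a pseudocount of 0.1 and limma without trend. Fits without the replicates numbered 2 and of recovered reads with edgeR and DESeq2, counts over label-checked genes alone, and the replicate block for the correlation of drug effects and for the drug sets in R5W were added after the data were seen. Comparisons with the same 3 DMSO libraries share chance values, so unchanged groups were simulated against those controls 10 times. Computation used R 4.3.3 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Genes sharing reads with paralogs or overlapping genes are named as uncertain where they occur.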

Results

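The data describe gene expression in 3 lymphoma lines treated with the BTK inhibitor ibrutinib or the RHOA inhibitor Rhosin, 3 libraries per group in 9 groups, and in TMD8 cells that carry RHOA WT or R5W under a PI3K inhibitor, 2 libraries per group. Drug libraries held 8911238 to 14153796 counts in TMD8, RIVA and HBL1, and R5W and WT libraries 19459885 to 21955743 recovered reads. RHOA, the gene changed by the knock-in, had log2 values of 13.83 and 13.7 in WT and 13.65 and 13.73 in R5W, which differed by -0.07 (SE 0.075, adjusted p = 0.531). These levels check expression only, because they carry no sequence of the altered codon. In the drug tables the RHOA row lay outside the segments with checked labels and held 468 to 1186 counts per library, so no RHOA level is given there.

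The first comparison asked which genes respond to Rhosin in TMD8. CD83, an activation marker of B cells and a target of NF-kB, fell by 3.32 on the log2 scale (SE 0.267, adjusted p = 1.02e-05), from 804.5 ± 57.4 to 80.5 ± 25.4 CPM (SD, n = 3). IRF4, a transcription factor that NF-kB induces and that this lymphoma type depends on, fell by 1.80 (SE 0.246, adjusted p = 0.000312). UHRF1, which maintains DNA methylation in dividing cells, fell by 2.01 (SE 0.222, adjusted p = 4.04e-05), and NOL6, a factor of ribosome assembly, by 2.09 (SE 0.202, adjusted p = 9.79e-06). SIT1, an adaptor that restrains antigen receptor signalling, rose by 1.54 (SE 0.226, adjusted p = 0.000351), from 291.9 ± 78.6 to 847.6 ± 116.2 CPM. The other genes that fell most were TXNDC5 (-2.42), NAT8L (-2.11) and ALDH1B1 (-1.96), and the others that rose most were LINGO3 (2.75), ATP8B3 (2.16), SHB (2.05), MXD4 (1.91) and GNA15 (1.5), with adjusted p from 2.2e-10 to 0.0292. TXNDC5 can share reads with an overlapping readthrough gene. GNA15 no longer passed without Rhosin replicate 2 (1.43), without Rhosin replicate 3 (1.36) or without DMSO replicate 3 (1.68).

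Single members of other lists were also label-checked in the Rhosin comparison of TMD8. TYMS, a G1/S gene that makes thymidylate, fell by 0.79 (adjusted p = 3.0e-06), and DNAJA1, a heat shock chaperone, by 1.23 (adjusted p = 3.02e-07). CD38, carried by plasma cells, rose by 1.06 (adjusted p = 0.000178), and VLDLR, a target of ATF4, by 0.81 (adjusted p = 0.000274). The actin and SRF/MRTF list had 4 such members, MYL12A, WDR1, CNN2 and TLN1, with a median of 0.04 and an unadjusted camera p of 0.595. Among the 452 label-checked genes tested, edgeR called 138 higher and 162 lower, which was 66.4%. Over all 11403 table rows tested it called 3014 higher and 3018 lower.

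Ibrutinib was compared with DMSO in TMD8 to find the genes under BTK control. CD83 fell by 2.83 (SE 0.261, adjusted p = 5.99e-05), to 112.9 ± 32.6 CPM from 804.5 ± 57.4 (SD, n = 3), and IRF4 fell by 1.24 (SE 0.243, adjusted p = 0.00418). CD274, which encodes the checkpoint ligand PD-L1, fell by 1.71 (SE 0.212, adjusted p = 0.000157), and KLF3, a repressor in B-cell development, by 1.57 (SE 0.134, adjusted p = 5.85e-08). SIT1 rose by 1.49 (SE 0.226, adjusted p = 0.000805), and MYOM1 rose by 1.23, from 137.1 ± 22.4 to 322.1 ± 12.9 CPM. NAT8L (-2.33), SPIRE1 (-1.83) and TXNDC5 (-1.59) completed the genes that fell most, and LINGO3 (1.87), CRB3 (1.65), PDZD2 (1.36) and ATP8B3 (1.12) those that rose most, with adjusted p from 5.03e-08 to 0.00166. DNAJA1 fell by 0.59 (adjusted p = 0.00128), and CD38 rose by 1.35 (adjusted p = 2.99e-05). TYMS was at -0.27 (adjusted p = 0.049), a call lost without Ibrutinib replicate 1 (-0.27), 2 (-0.16) or 3 (-0.32) and without DMSO replicate 1 (-0.25) or 3 (-0.21). The actin and SRF/MRTF members had an unadjusted camera p of 0.223. Ibrutinib raised 76 and lowered 144 of the 452 label-checked genes, and raised 1946 and lowered 2274 of the 11403 table rows.

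**Figure D1:**
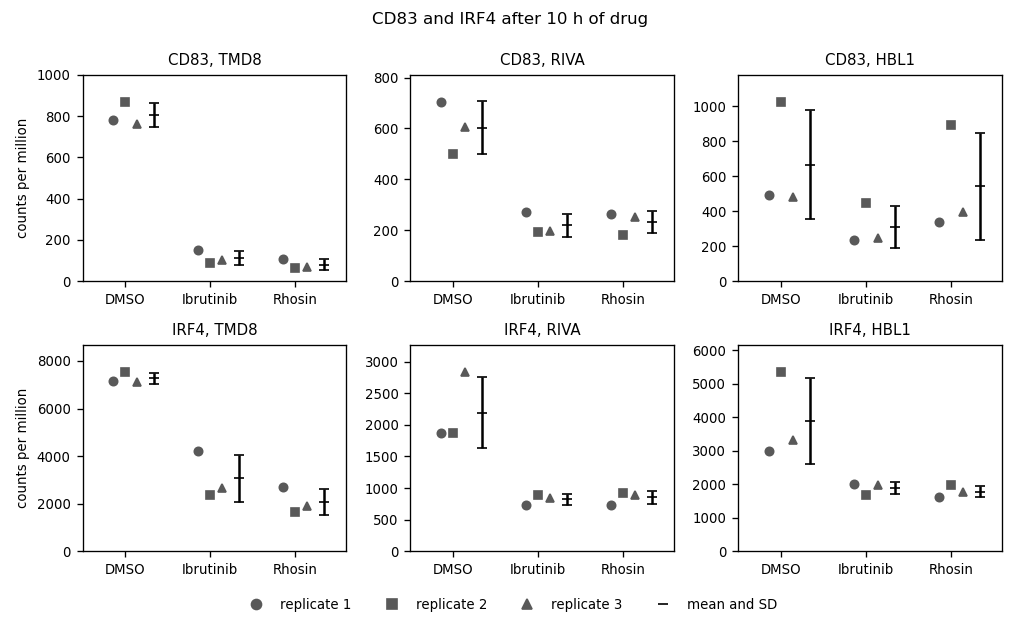
CD83 and IRF4 levels in CPM for each library of TMD8, RIVA and HBL1 under DMSO, ibrutinib and Rhosin, with points marked by replicate and lines for mean and SD (n = 3). In TMD8 the mean of CD83 was 804.5 CPM under DMSO, 112.9 under ibrutinib and 80.5 under Rhosin.

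Set directly against ibrutinib in TMD8, Rhosin gave higher SHB, an adaptor of receptor tyrosine kinases, by 1.84 (SE 0.141, adjusted p = 1.64e-07), at 39.3 ± 5.74 against 11 ± 1 CPM (SD, n = 3). MXD4, a MAX partner that opposes MYC, was higher by 0.91 (SE 0.132, adjusted p = 0.000289) and HSD11B1L by 0.89 (adjusted p = 0.000331). CCT5, a subunit of the chaperonin that folds actin and tubulin, was at -0.74 (adjusted p = 4.91e-05), and ALDH1B1 at -0.82 (adjusted p = 0.000151). For CD83 and IRF4 the difference between the drugs was -0.49 (adjusted p = 0.268) and -0.56 (adjusted p = 0.181), and with the replicate numbers as a block it passed (adjusted p = 0.0224 and 0.00396). Without Rhosin replicate 1 both genes also passed, at -0.77 for CD83 and -0.78 for IRF4. The actin and SRF/MRTF members had an unadjusted camera p of 0.559. Of the 452 label-checked genes 52 were higher and 46 lower under Rhosin, in all 98, and of the table rows 614 were higher and 698 lower, in all 1312. The block gave 2020 rows. Leaving out Rhosin replicate 2 gave 617 rows and 54 label-checked genes, and leaving out Ibrutinib replicate 1 gave 642 and 52.

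CD83 and SIT1 were among the genes that both drugs moved in 1 direction in TMD8. Of the label-checked genes, 73 were higher under both drugs, where independent lists would share 23.2, and 127 lower under both, against 51.6, with 0 called in opposite directions by edgeR. Genes moved in opposite directions numbered 6 among all table rows, where 1771 rows were higher and 2057 lower under both, against 514.4 and 601.9 for independent lists. Across label-checked genes the effects of the drugs correlated with Pearson's r of 0.915, and across table rows 0.901, while unchanged groups simulated against the same DMSO libraries gave 0.53 and 0.521 on average and at most 0.63 and 0.53. The covariance was 0.436 in label-checked genes against 0.0152 simulated, a difference of 0.421, and 0.55 in rows against 0.0285, a difference of 0.522. Genes are not independent replicates, and 3 controls cannot be split into groups of at least 2 libraries, so part of the excess of r may come from the shared controls. Independent lists are not the no-change value for comparisons that share controls. The simulated unchanged groups had 0 label-checked genes and 0 rows called by edgeR under both drugs in each of 10 simulations. With no gene changed the threshold leaves almost no calls for either drug, so this 0 was largely fixed in advance. It does not measure the overlap that shared controls add among many called genes.

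In RIVA, another line of this lymphoma type, Rhosin was compared with DMSO in the same way. IRF4 fell by 1.37 (SE 0.156, adjusted p = 0.000147), from 2194 ± 561.2 to 850.4 ± 98.2 CPM (SD, n = 3), and CD83 by 1.37 (SE 0.173, adjusted p = 0.000359). BMP6, a secreted growth factor, fell by 1.67 (SE 0.168, adjusted p = 3.08e-05), and CD72, an inhibitory co-receptor of B cells, by 1.12 (SE 0.13, adjusted p = 8.94e-05). ALDH5A1, an enzyme of GABA breakdown, rose by 1.0 (SE 0.098, adjusted p = 2.58e-05), from 1851 ± 155.3 to 3713 ± 369.2 CPM. Its row held 67.54 to 72.72 CPM in TMD8 DMSO, and the level check was made in TMD8 alone, so its name is uncertain in RIVA. GCNT2 (-1.12) and PDZD2 (-1.02) also fell, and LINGO3 (1.39), HCN2 (1.07), IL11RA (0.94), PNPLA2 (0.90) and LRRC56 (0.89) rose, with adjusted p from 2.6e-05 to 0.0117. PDZD2 is uncertain in the same way, at 143.8 CPM in RIVA DMSO against 7.64 to 10.07 in TMD8 DMSO. The actin-severing cofactor WDR1 fell by 0.48 (adjusted p = 0.00182). With CNN2 (-1.34), TLN1 (-0.25) and MYL12A (-0.07), which did not pass, it made up the actin and SRF/MRTF list. The camera p of this list, unadjusted because only 1 list was tested, was 0.0425, and 0.203 with an estimated correlation. CNN2 passed without DMSO replicate 1 (-1.59). DNAJA1 fell by 0.73 (adjusted p = 0.00922).

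Rhosin raised 54 and lowered 82 of the 460 label-checked genes tested in RIVA, in all 136, and raised 1019 and lowered 1016 of 11956 table rows, in all 2035. Rows numbered 1178 without Rhosin replicate 2, 1322 without Rhosin replicate 3 and 1139 without DMSO replicate 1, and label-checked genes 89 without Rhosin replicate 2.

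Under ibrutinib in RIVA, IRF4 fell by 1.42 (SE 0.156, adjusted p = 0.00119), to 820.1 ± 84.2 CPM from 2194 ± 561.2 (SD, n = 3), and CD83 fell by 1.46 (SE 0.174, adjusted p = 0.00184). BMP6 fell by 1.40 (SE 0.166, adjusted p = 0.00119), GADD45B, a stress gene that NF-kB induces, by 1.05 (SE 0.149, adjusted p = 0.00316), and PDZD2 by 0.83. ALDH5A1 rose by 0.66 (SE 0.097, adjusted p = 0.00389). HIVEP1 fell by 0.67 (adjusted p = 0.00919) and BTN1A1 rose by 0.89 (adjusted p = 0.00861), and neither passed without Ibrutinib replicate 3 (-0.71 and 0.85). STX18 rose by 0.46 (adjusted p = 0.0434), and did not pass without Ibrutinib replicate 1 (0.44), 2 (0.50) or 3 (0.46), nor without DMSO replicate 1 (0.49) or 3 (0.35). Its row held 253.7 CPM in RIVA DMSO against 9.83 to 12.12 in TMD8 DMSO, so its name too is uncertain in RIVA. In all, 3 label-checked genes were higher and 10 lower, of 460, and 49 and 61 of the table rows, together 110. Rows numbered 31 without Ibrutinib replicate 3, 64 without DMSO replicate 1 and 69 without DMSO replicate 3, and label-checked genes 7 without Ibrutinib replicate 3. The actin and SRF/MRTF members had an unadjusted camera p of 0.784.

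Against ibrutinib in RIVA, Rhosin gave lower GMDS, an enzyme of fucose synthesis, at -0.92 (SE 0.089, adjusted p = 8.42e-05), and lower PAX5, the factor that maintains B-cell identity, at -0.60 (SE 0.092, adjusted p = 0.00187). CCT5 was at -0.75 (SE 0.115, adjusted p = 0.00188). SPIRE1, an actin nucleator, was higher by 1.01 (SE 0.124, adjusted p = 0.000481) and ANO9 by 0.55 (adjusted p = 0.00215). CD83 and IRF4 differed by 0.09 (adjusted p = 0.808) and 0.05 (adjusted p = 0.872). The actin and SRF/MRTF list had an unadjusted camera p of 0.0168, and of 0.142 with an estimated correlation. Within it WDR1 was at -0.34 (adjusted p = 0.0229). WDR1 did not pass without Rhosin replicate 1 (-0.33), 2 (-0.33) or 3 (-0.37) or without Ibrutinib replicate 3 (-0.33). Of 460 label-checked genes 38 were higher and 42 lower, in all 80, and of the table rows 569 were higher and 559 lower, in all 1128. Rows numbered 498 without Rhosin replicate 2, 500 without Rhosin replicate 3 and 409 without Ibrutinib replicate 3, and label-checked genes 35, 34 and 29.

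CD83 and IRF4 were among 8 label-checked genes that both drugs lowered in RIVA, against 1.8 for independent lists. Genes higher under both numbered 3 against 0.4, and 1 was called in opposite directions. The effects of the drugs correlated with r of 0.578 across label-checked genes and 0.554 across rows, against averages of 0.464 and 0.492 and highest values of 0.563 and 0.501 simulated with the shared controls. With the replicate block r was 0.565 in label-checked genes, below the highest simulated value of 0.676, and 0.547 in rows, where the highest was 0.513. The covariance without the block was 0.0936 in label-checked genes against 0.0197 simulated, a difference of 0.0739, and 0.0952 in rows against 0.0341, a difference of 0.0611. Part of the excess may come from the shared controls here too. The simulated groups again had 0 genes and 0 rows called under both drugs by edgeR, which was largely fixed in advance here as well.

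In HBL1 the libraries numbered 2 stood apart in every group, and without the replicate block edgeR passed 0 of 463 label-checked genes in each of the 3 comparisons. IRF4 had a log2 fold change of -1.13 (SE 0.21, adjusted p = 0.0754) under Rhosin and -1.04 (SE 0.21, adjusted p = 0.138) under ibrutinib. At an unadjusted p under 0.05 there were 119 label-checked genes for Rhosin, 41 for ibrutinib and 54 between the drugs, and DESeq2 called 29, 3 and 8. Of 11905 table rows edgeR called 4, 13 and 0, with 2045, 980 and 1173 at an unadjusted p under 0.05, and DESeq2 called 405, 103 and 84. The 4 Rhosin rows became 0 without Rhosin replicate 1 or 3 or any of DMSO replicates 1, 2 and 3. The 13 ibrutinib rows became 0 without any 1 of the ibrutinib replicates or without DMSO replicate 1 or 3, and 7 without DMSO replicate 2, and the 0 between the drugs became 1 without Rhosin replicate 2. The actin and SRF/MRTF members had unadjusted camera p of 0.605, 0.943 and 0.549.

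With the replicate numbers as a block, IRF4 in HBL1 fell by 1.10 under Rhosin (SE 0.217, adjusted p = 0.0188), to 1777 ± 176 CPM from 3882 ± 1287 (SD, n = 3). CD83, added after its values were seen, was at -0.34 under Rhosin (SE 0.08, adjusted p = 0.00353), and at -0.30 without the block (adjusted p = 0.768), which became 0.15 without DMSO replicate 2. TERT, the telomerase subunit, fell by 1.19 (SE 0.149, adjusted p = 5.46e-05), and NOL6 by 0.84 (SE 0.068, adjusted p = 6.91e-08). CD38 rose by 1.17 (SE 0.092, adjusted p = 7.81e-08) and MXD4 by 1.11 (SE 0.153, adjusted p = 9.93e-05). PAK1IP1 (-0.97), LPCAT1 (-0.77) and ALDH1B1 (-0.75) also fell, and CAPS (1.04), LRRC56 (0.96), RECK (0.95) and LY86 (0.89) rose, with adjusted p from 1.19e-07 to 0.000329. Under ibrutinib CD83 fell by 1.08 (SE 0.081, adjusted p = 1.43e-08), to 308.7 ± 119.8 from 666.6 ± 311.9 CPM. IRF7, a regulator of interferon genes, fell by 0.89 (SE 0.075, adjusted p = 7.65e-08) and CD274 by 0.59 (SE 0.1, adjusted p = 0.000539), while IRF4 did not pass (adjusted p = 0.0565). CD151 (-0.71), TNIP2 (-0.57) and FRMPD1 (-0.56) fell as well, and ALDH5A1 (0.85), CD38 (0.84), LY86 (0.73), LRRC56 (0.71), VMAC (0.59) and TMEM129 (0.50) rose, with adjusted p from 4.56e-06 to 0.0137.

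Between the drugs, the blocked fit of HBL1 had CD83 higher under Rhosin by 0.75 (SE 0.081, adjusted p = 5.41e-06), JAK2, a cytokine receptor kinase, by 0.68 (SE 0.09, adjusted p = 6.15e-05) and SRD5A1 by 0.67 (adjusted p = 1.83e-05). NOL6 was at -0.55 (adjusted p = 2.58e-05). TUBB2A was at 1.19 (adjusted p = 6.47e-05) and can share reads with other tubulin genes. The block gave 89 label-checked genes higher and 116 lower for Rhosin, 19 and 47 for ibrutinib, and 69 and 50 between the drugs. Among table rows it gave 1376 higher and 1685 lower for Rhosin, 489 and 566 for ibrutinib, and 725 and 831 between the drugs. Without the block, the drug effects across genes correlated with r of 0.616 (label-checked) and 0.606 (rows), against averages of 0.482 and 0.499 and highest values of 0.569 and 0.524 simulated without replicate effects. The covariance was 0.0884 and 0.101, against 0.0381 and 0.0526 simulated, differences of 0.0503 and 0.0482. With the block and replicate effects simulated, r was 0.613 and 0.605 against averages of 0.511 and 0.497 and highest values of 0.578 and 0.515, and the differences in covariance were 0.0737 and 0.0756. For genes lower under both drugs without the block, the overlap was 1 row against 0 for independent lists, and part of any excess may come from the shared controls.

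Whether a drug acted differently in the 3 lines was tested by interaction terms in the model of all 27 libraries. The Rhosin effect on SHB was 2.14 (SE 0.181) in TMD8, -0.32 (SE 0.206) in RIVA and -0.16 (SE 0.261) in HBL1 (adjusted p = 1.15e-06 for the difference). SPIRE1 had -1.53, 0.41 and 0.33 in TMD8, RIVA and HBL1 (adjusted p = 1.98e-07), and NAT8L, which makes N-acetylaspartate, had -2.01, 0.27 and 0.00 (adjusted p = 1.31e-06). KANK1, a regulator of actin at the cell edge, had -1.19, 0.24 and 0.32 (adjusted p = 1.4e-06), and TXNDC5 had -2.33, -0.53 and -0.47 (adjusted p = 1.98e-07). For ibrutinib, PDZD2 had 1.43 in TMD8, -0.82 in RIVA and 0.45 in HBL1 (adjusted p = 5.27e-05), and RHOH -0.80, 0.24 and 0.37 (adjusted p = 0.000136). NAT8L had -2.26, -0.07 and -0.71 (adjusted p = 6.15e-05), TXNDC5 -1.52, -0.31 and -0.40 (adjusted p = 0.000347) and KANK1 -0.81, 0.31 and 0.19 (adjusted p = 0.000426).

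The Rhosin effect differed between lines for 92 of 512 label-checked genes and 1660 of 14367 table rows, and the ibrutinib effect for 36 and 590. By pairs of lines, Rhosin gave 98 label-checked genes for TMD8 against RIVA, 62 for TMD8 against HBL1 and 4 for RIVA against HBL1, and 197, 149 and 44 once replicates were blocked within lines. Ibrutinib gave 53, 18 and, by edgeR, 0, and with this block 158, 92 and 13. The numbers met the pairing rule in every comparison of HBL1, in some of TMD8 and in none of RIVA. The block raised the label-checked genes to 212 for Rhosin and 151 for ibrutinib, and the rows to 3661 and 2290.

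R5W was compared with WT under copanlisib to ask how expression differs between these cells while PI3K is inhibited. The labels do not say how many clones each genotype came from and mark no second R5W clone. In all R5W results below, effects of the RHOA change therefore cannot be told apart from clonal differences. TNF, the cytokine and NF-kB target, rose by 2.41 (SE 0.176, adjusted p = 2.01e-06), at values of 848 and 566.1 in R5W against 121.9 and 136.8 in WT (n = 2). PEG10, a retrotransposon-derived gene, rose by 2.84 (SE 0.192, adjusted p = 1.08e-05), and FERMT2, a kindlin that activates integrins, by 2.55 (SE 0.116, adjusted p = 6.54e-08). XAF1, an interferon-induced promoter of apoptosis, fell by 2.37 (SE 0.157, adjusted p = 8.14e-07), and SLC7A11, the cystine transporter, by 2.12 (SE 0.139, adjusted p = 9.06e-06), from 3962 and 3519 to 727.6 and 1008. ALDH7A1 (2.63), OLFML2A (2.00) and MAGEB2 (1.90) also rose, and OTOF (-3.68), HLA-DRB5 (-2.54), L1CAM (-2.33) and HLA-DQA2 (-2.31) fell, with adjusted p from 6.8e-08 to 7.8e-06. HLA-DRB5 and HLA-DQA2 can share reads with their paralogs and are uncertain. Of 13698 genes tested by limma, 1794 rose and 1634 fell, in all 3428, of which 283 and 280 changed at least 2-fold. The count was 5668 without R5W replicate 2, 1024 without WT replicate 1 and 1205 without WT replicate 2, and limma without trend gave 857. Of the genes named for R5W below, SYK, PIK3AP1, E2F1, AURKB, CXCL10, SPIB, HSPA4L, LSS, HSPA5, HMOX1, VCL, BMF, PMAIP1, SLC2A3, UHRF1, NOL6 and MXD4 did not pass without the trend.

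NF-kB target genes were higher in R5W, 17 of 25 measured against 2 lower, and 18 and 2 adjusted over the list alone (list adjusted p = 8.1e-10, and adjusted p = 0.405 with an estimated correlation). IRF4 rose by 0.91 (SE 0.067, adjusted p = 1.46e-06), NFKBIZ by 0.91 (SE 0.079, adjusted p = 5.73e-06) and the chemokine CCL22 by 2.37 (SE 0.239, adjusted p = 2.02e-05), alongside TNF. In the immediate response to BCR and MAPK signals 7 of 18 genes were higher and 2 lower, 7 and 3 adjusted over the list alone, with MYC at 1.13 (SE 0.074, adjusted p = 8.14e-07), DUSP2 at 1.07, IER3 at 0.95 and SPRED2 at 0.68. Its list test gave an adjusted p of 0.058, and adjusted p = 0.506 with an estimated correlation. BCR signalling components were lower, 12 of 24 against 1 higher, and 13 and 1 adjusted over the list alone (adjusted p = 1.57e-05, and adjusted p = 0.405 with an estimated correlation). LAT2, an adaptor of antigen receptors, fell by 0.78 (SE 0.097, adjusted p = 8.99e-05), the kinase SYK by 0.52 and the PI3K adaptor PIK3AP1 by 0.53, while BTK was at -0.18 (adjusted p = 0.0913). BTK passed without R5W replicate 2 (-0.24).

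**Figure D2:**
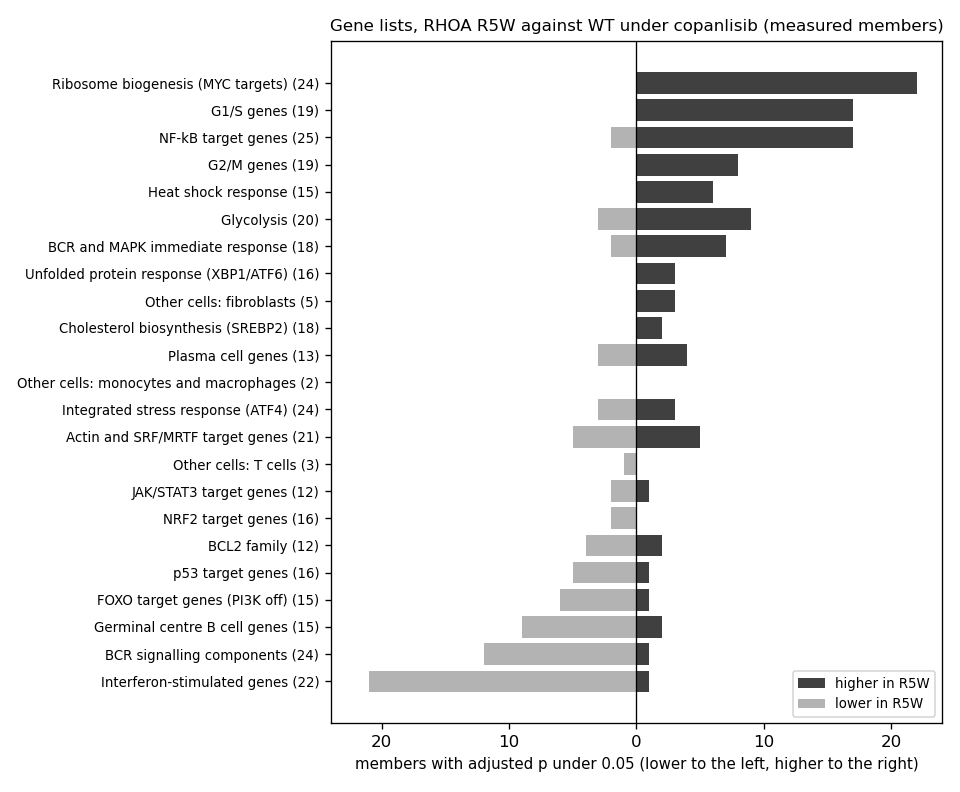
Number of members with adjusted p under 0.05 that were higher (right) or lower (left) in R5W than in WT for each gene list, with measured members in brackets (limma, n = 2 per group). Interferon-stimulated genes had 21 of 22 members lower and ribosome biogenesis genes 22 of 24 higher.

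FOXO targets, which PI3K signalling keeps low, were lower in R5W, 6 of 15 against 1 higher, and 9 and 1 adjusted over the list alone (adjusted p = 0.000346, and adjusted p = 0.484 with an estimated correlation). TXNIP, which restrains glucose uptake, fell by 1.46 (SE 0.095, adjusted p = 8.14e-07) and KLF2, a factor of quiescence, by 1.34 (SE 0.094, adjusted p = 1.04e-06), while FOXO1 was at -0.11 (adjusted p = 0.404). Ribosome biogenesis genes, which MYC drives, were higher, 22 of 24 and 0 lower, and 23 and 0 adjusted over the list alone (adjusted p = 1.5e-13, and adjusted p = 0.455 with an estimated correlation). MRTO4 rose by 0.67, DKC1 by 0.62, GNL3 by 0.57 and NOLC1 by 0.54, with adjusted p from 7.36e-05 to 0.000167. G1/S genes were higher too, 17 of 19, the same number adjusted over the list alone (adjusted p = 9.6e-12, and adjusted p = 0.455 with an estimated correlation), among them CDC25A (0.90), CCNE1 (0.88), GINS2 (0.90) and E2F1 (0.76). Of 19 G2/M genes 8 were higher, 11 adjusted over the list alone (adjusted p = 0.000217, and adjusted p = 0.455 with an estimated correlation), with AURKB at 0.59 (adjusted p = 0.00132).

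Interferon-stimulated genes were lower in R5W, 21 of 22, with 1 higher, and the same numbers adjusted over the list alone (adjusted p = 5.7e-16, and adjusted p = 0.405 with an estimated correlation). MX1, which blocks viral replication, fell by 1.26 (SE 0.086, adjusted p = 8.99e-07), IFIT2 by 1.74 (SE 0.145, adjusted p = 3.89e-06) and STAT2 by 0.79 (SE 0.076, adjusted p = 1.14e-05), while the chemokine CXCL10 rose by 1.17 (adjusted p = 0.0103), a call lost without WT replicate 1 (0.76). Germinal centre genes were lower, 9 of 15 against 2 higher, the same numbers adjusted over the list alone (adjusted p = 0.000346, and adjusted p = 0.455 with an estimated correlation), with LMO2 at -0.77, BCL7A at -0.60 and SPIB at -0.55, and MME higher by 2.23. Of 13 plasma cell genes 4 were higher and 3 lower, 4 and 4 adjusted over the list alone (adjusted p = 0.552), with ELL2 at 1.10, SLAMF7 at 1.29, SDC1 at 0.99 and IGJ at -0.62. Its median was -0.02 and its mean 0.16.

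Heat shock genes were higher in 6 of 15, 7 adjusted over the list alone (adjusted p = 0.000622, and adjusted p = 0.491 with an estimated correlation), with HSPA4L at 0.70 (adjusted p = 0.00051). Cholesterol biosynthesis had 2 of 18 genes higher, LSS (0.49) among them, also adjusted over the list alone (adjusted p = 0.0367, and adjusted p = 0.754 with an estimated correlation). LSS did not pass without WT replicate 2 (0.39). The integrated stress response had 3 of 24 higher and 3 lower, the same adjusted over the list alone (adjusted p = 0.583), SLC7A11 among the latter. The unfolded protein response had 3 of 16 higher (adjusted p = 0.141), with HSPA5 at 0.26 (adjusted p = 0.0181), which did not pass without WT replicate 1 (0.30) or WT replicate 2 (0.23). NRF2 targets had 2 of 16 lower (adjusted p = 0.863), with HMOX1 at -1.11, and a median of 0.03 beside a mean of -0.01.

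Actin and SRF/MRTF targets had 5 of 21 higher and 5 lower, 7 and 7 adjusted over the list alone (adjusted p = 0.723), with TAGLN2 at 0.68, TAGLN at -1.52 and VCL at -0.64. Of 16 p53 targets 1 was higher and 5 lower (adjusted p = 0.0705), with BTG2 at -0.59 and BBC3 at -0.71, and of 12 BCL2 family genes 2 were higher and 4 lower (adjusted p = 0.268), with HRK at -1.32, PMAIP1 at 0.57 and BMF at -0.62. JAK/STAT3 targets had 1 of 12 higher and 2 lower, 2 and 4 adjusted over the list alone (adjusted p = 0.255). Glycolysis genes had 9 of 20 higher and 3 lower, the same adjusted over the list alone (adjusted p = 0.141), with SLC16A1 at 0.91, HK2 at 0.65, ENO2 at 0.88 and SLC2A3 at -3.07, a median of 0.11 and a mean of -0.06. Genes that mark other cells showed CD8A at -0.88 as 1 of 3 T-cell genes (adjusted p = 0.713), a call lost without WT replicate 1 (-0.89) or WT replicate 2 (-0.87). Of 2 monocyte genes measured limma called 0, with ITGAM at -0.60 and MNDA at -0.23, which passed without R5W replicate 2 (-0.77 and -0.40), and too few were measured for a list test. Of 5 fibroblast genes COL1A2 (1.57), COL1A1 (1.33) and PDGFRB (2.03) were higher (adjusted p = 0.00307, and adjusted p = 0.455 with an estimated correlation). For the unfolded protein response, NRF2, p53, BCL2 family, T-cell, monocyte and fibroblast lists the counts adjusted over the list alone were the same.

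The last comparison asked where genes that the drugs moved in TMD8 lay in R5W against WT. Of 51 label-checked genes that Rhosin lowered at least 2-fold, 36 were higher in R5W and 0 lower by limma, with a median of 0.39 (adjusted p = 2.5e-14, and adjusted p = 0.12 with an estimated correlation). Among them CD83 rose by 0.77 (SE 0.086, adjusted p = 4.15e-05), ALDH1B1 by 0.79 (SE 0.091, adjusted p = 4.96e-05), UHRF1 by 0.61 (SE 0.113, adjusted p = 0.00211) and NOL6 by 0.47 (SE 0.089, adjusted p = 0.00187). UHRF1 and NOL6 did not pass without WT replicate 1 (0.54 and 0.43). Of 36 genes that Rhosin raised, 11 were lower and 1 higher (adjusted p = 0.00288, and adjusted p = 0.12 with an estimated correlation), SIT1 (-0.70) and MXD4 (-0.60) being lower. MXD4 did not pass without WT replicate 2 (-0.51). Of 14 genes that ibrutinib lowered, 11 were higher and 0 lower by limma (adjusted p = 2.7e-07, and adjusted p = 0.12 with an estimated correlation), and of 13 that it raised 1 was higher and 3 lower (adjusted p = 0.15). Across 438 genes the fold changes for R5W against WT correlated with those for Rhosin at r = -0.493 and those for ibrutinib at r = -0.502. These genes are not independent replicates.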

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

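The tests of differences between lines, of reads from other lines and of expression level were planned or set out before their results were seen; all others in this part were chosen only after the result was seen.

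Responses to both drugs differed between the cell lines by a test of the difference itself. The Rhosin effect differed for 92 of 512 label-checked genes and 1660 of 14367 table rows, and the ibrutinib effect for 36 and 590. For Rhosin the smallest adjusted p-values under the naming rule were those of SPIRE1 (1.976e-07), TXNDC5 (1.976e-07), SHB (1.145e-06), NAT8L (1.306e-06) and KANK1 (1.397e-06). SHB rose in TMD8 (2.14) and had -0.32 in RIVA and -0.16 in HBL1, while SPIRE1, TXNDC5, NAT8L and KANK1 fell in TMD8 by 1.53, 2.33, 2.01 and 1.19. For ibrutinib they were those of PDZD2 (5.27e-05), NAT8L (6.153e-05), RHOH (0.0001361), TXNDC5 (0.0003472) and KANK1 (0.0004263). PDZD2 was at 1.43 in TMD8 and -0.82 in RIVA, and RHOH at -0.80 in TMD8 and 0.24 in RIVA.

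Treatment labels were redrawn within each line 25 times, the real labels included, and the number of draws was raised from 20 after the first result. For each drug 3 of the 25 label sets, the real one among them, gave as many table rows, and 3 as many label-checked genes, so chance was not excluded by this count. The highest other set gave 4446 rows and 244 label-checked genes for Rhosin and 1381 and 71 for ibrutinib. Both other sets as large kept or fully swapped the labels of a line, which keeps its whole drug effect and so builds a difference between lines. Of the draws, 5 for Rhosin and 4 for ibrutinib did so, and the highest of the rest gave 0 rows and 0 label-checked genes by edgeR. The rest mixed drug and DMSO libraries in every line. A drug effect then adds to the spread and can lower the count, so these counts do not measure what chance gives.

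GAPDH, MYC and TUBA1B held 0 counts in the TMD8 DMSO libraries beside WT log2 values of 15, 11.36 and 13.31, and across 14858 genes rho between counts and levels was 0.106. Of the 100 most abundant genes of the log2 table, 50% held under 10 counts in TMD8 DMSO, which argues against expression differences between the 2 sets of TMD8 libraries. In a scan of 239 blocks of 10 Mb, 72 of 174 neighbouring pairs shared their best shift within 5 kb, against 37 with permuted levels and 2 with mirrored positions, the mirrored comparison being chosen after the permuted one had missed a bound of 3 times. Among blocks outside the segments 65 of 162 pairs shared it, against at most 2 in 5 draws with the counts shuffled among a block's rows, which argues against rows shuffled against their IDs. A candidate explanation is that read positions and gene coordinates came from different genome builds, which stays open without the reads. Apart from expression differences between the 2 sets, no biological explanation was tested.

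In HBL1 the libraries numbered 2 lay apart from those numbered 1 and 3 on the first principal component (43.4% of variance), at 20.5, 35.2 and 49.6 against -0.2 or less. In them TYMS (-1.48), UHRF1 (-1.46) and NDC80 (-1.45) were lower and MXD4 (1.35), CD72 (1.33) and CD83 (1.09) higher than in the other numbers, on the log2 scale. Sequencing depth is argued against, since the library numbered 2 held the highest total in 2 of 3 groups and the lowest in the ibrutinib group, and so are reads from TMD8 or RIVA cells, whose share was at most 0.014%. A culture or handling batch shared by libraries of 1 number may explain it, and all same-numbered pairs deviated together with a correlation of at least 0.29. Libraries numbered 1 and 3 of different treatments also did so, at 0.23 to 0.3. When number 2 stands apart, numbers 1 and 3 deviate together from their group means by construction. Their correlations alone therefore cannot show whether the numbers pair these libraries. The labels name no such batch, and a different state of the cells in that batch was not tested.

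Genes that Rhosin lowered in TMD8, such as CD83 and ALDH1B1, were higher in R5W, with a median of 0.39 over 51 genes. That median lay at percentile 100 of 10000 sets matched on level, whose highest was 0.217, which argues against expression level as the cause. Genes that ibrutinib lowered were higher too, with a median of 0.78 over 14 genes. With up to 100 of the most changed genes the medians were 0.27 for those lowered by ibrutinib and 0.28 for those lowered by Rhosin, and across 438 genes the R5W fold changes correlated with those of ibrutinib at r = -0.502 and of Rhosin at r = -0.493, so the shift was not particular to Rhosin. Opposite effects of R5W and of a response that both drugs share may explain it, and so may clonal differences between the R5W and WT cells other than RHOA. The labels do not say how many clones each genotype came from and mark no second R5W clone, so these cannot be told apart. With the correlation between genes estimated from the 4 libraries, the set gave an adjusted p of 0.1204.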

How the results depend on the processing

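Fits without the replicates numbered 2 and on recovered reads, counts over label-checked genes alone, and the replicate block for the correlation of drug effects and for the drug sets in R5W were chosen only after the results were seen; the other alternatives were planned.

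Of the counts, correlations and sets under their alternatives, 220 stayed, 105 moved, 3 became weaker and 2 stronger. Counts stayed if within 1.5 times, and sets if on their side of the threshold. Correlations stayed if they differed by no more than the SD of the values without 1 DMSO replicate, so small shifts count as moved. Of list tests 48 kept their side, 14 became weaker and 2 stronger. Of single genes, among them list members that the report does not name, 4154 values kept their side of the threshold, 149 became weaker, 154 stronger and 1 reversed, without R5W replicate 2. A reversal was counted only where the gene passed in either fit. Values that changed sign without passing, such as CD83 under Rhosin in HBL1, count as kept. For R5W, 44 of these genes no longer passed by limma without trend, 27 without WT replicate 1 and 21 without WT replicate 2. A group left with 1 library is assumed to vary like the others.

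The replicate block gave 2020 rows for Rhosin against ibrutinib in TMD8, 277 rows and 23 label-checked genes for ibrutinib in RIVA, and 2013 and 144 for Rhosin against ibrutinib in RIVA. In HBL1 it gave 3061 rows and 205 label-checked genes for Rhosin, 1055 and 66 for ibrutinib, and 1556 and 119 between the drugs; between lines it gave 3661 and 212 for Rhosin and 2290 and 151 for ibrutinib. Removing a spread shared by same-numbered libraries would raise counts in HBL1, where simulated recovery at 2-fold was 35.8% without and 64.2% with the block. For R5W, whose numbers do not pair (correlation of deviations -0.06), the block gave 3713 genes, an adjusted p of 0.00736 for the BCR and MAPK list and 0.0426 for the integrated stress response, and for the set raised by ibrutinib 0.01209. In RIVA, where the numbers did not meet the pairing rule, the actin list had an unadjusted camera p of 0.0551 with the block for Rhosin against DMSO. It changed no other call of a list or set.

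Without the replicates numbered 2, rows numbered 2516 for ibrutinib in TMD8, 484 (47 label-checked genes) for Rhosin against ibrutinib in TMD8 and 423 (32) in RIVA, fewer samples being one reason. In HBL1 they numbered 1730 (132), 278 (24) and 851 (80) for Rhosin, ibrutinib and between the drugs. DESeq2 gave 200 (20) for ibrutinib in RIVA and 405 (29), 103 (3) and 84 (8) in HBL1. No low-count filter gave 317 (25) for ibrutinib in RIVA and 572 (43), 126 (6) and 109 (14) in HBL1, and the stricter filter 7 rows for ibrutinib in HBL1. The 6 compared libraries alone gave 0 rows for Rhosin in HBL1 by edgeR and 2 for ibrutinib. The cause was not tested for these.

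A log2 fold limit of 1 gave, by its construction, fewer calls: in TMD8 2311 (93) for Rhosin, 1174 (30) for ibrutinib and 186 (9) between them, in RIVA 454 (19), 52 (5) and 212 (7), and for R5W 563. For R5W limma without trend gave 857 genes, and the cause was not tested. Quantile normalization gave 3448, no filter 3569, a stricter filter 3415, a pseudocount of 0.1 3402, and on recovered reads edgeR 3459, edgeR with RLE 3479 and DESeq2 2605.

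Leaving out 1 replicate at a time gave 617 to 1205 rows (52 to 92 label-checked) for Rhosin against ibrutinib in TMD8. In RIVA it gave 1139 to 1948 (89 to 138) for Rhosin, 31 to 115 (7 to 15) for ibrutinib and 409 to 970 (29 to 72) between them. In HBL1 it gave 0 to 4 for Rhosin, 0 to 7 for ibrutinib and 0 to 1 between them, and for R5W 1024 to 5668 genes. The correlation between drug effects without 1 DMSO replicate ran from 0.889 to 0.903 in TMD8 rows (label-checked 0.906 to 0.923), 0.539 to 0.655 in RIVA (0.509 to 0.686) and 0.621 to 0.756 in HBL1 (0.587 to 0.847). At 10 CPM or more it was 0.934 in TMD8 rows, 0.928 in label-checked genes and 0.623 in RIVA rows; Spearman's rho was 0.89 and 0.933 in TMD8 and 0.46 and 0.484 in RIVA.

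With an estimated correlation the sets raised or lowered by Rhosin and lowered by ibrutinib had an adjusted p of 0.1204 in R5W against WT, and the list calls lost in this way are given beside each list. With the 100 most changed genes per direction the set raised by ibrutinib had 0.0001181, and 0.2407 with an estimated correlation. The correlation is estimated from 4 libraries, which in this form of the test also set the degrees of freedom. For the set raised by Rhosin at least 2-fold the estimated correlation was 0.009, below the preset 0.01, and the call was still lost. A lost call therefore does not by itself show that the genes vary together. Depth set the limit for genes under the filter, which were not tested.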

Other observations

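The class II test, the choice of SEPW1 and the tests on other splits of the libraries were chosen only after the results were seen.

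Genes of MHC class II, which present antigen to T cells, were lower in R5W than in WT, 14 of 14, with a median of -1.36 on the log2 scale. HLA-DRA fell by 0.93 (SE 0.073), CD74 by 0.65 (SE 0.075) and HLA-DPB1 by 1.42 (SE 0.082). CIITA, their master regulator, fell by 0.43 (adjusted p = 0.00199) and did not pass without WT replicate 1 (-0.46) or WT replicate 2 (-0.40), nor by limma without trend. Tested as a list after it was noticed, the group gave a camera p of 1.9e-19 unadjusted and 0.0339 with an estimated correlation. Genes of the HLA-DR and HLA-DQ groups can share reads with each other.

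SEPW1, a small selenoprotein gene chosen after its values were seen, had values of 1.23 and 1.32 in R5W, about 1 read each, and 174.7 and 187.4 in WT. CXCL10 was the 1 interferon-stimulated gene that rose in R5W while 21 fell; its call was lost without WT replicate 1 (0.76) and by limma without trend.

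Each drug comparison has 10 splits of its 6 libraries into 3 and 3, too few for a share under 0.05. Every split but the real one mixes treatments in both groups. A drug effect then adds to the spread within groups and can lower the count, so these counts do not measure what chance gives. In TMD8 the real labels gave 6032 rows and 300 label-checked genes for Rhosin, 4220 and 220 for ibrutinib and 1312 and 98 between the drugs, and the highest other split 0 in each, so that 1 split was as large. In RIVA they gave 2035 and 136, 110 and 13, and 1128 and 80, and the highest other split 0 except 1 row for ibrutinib. In HBL1 the real labels gave 4 and 13 rows for Rhosin and ibrutinib, with 0 for the highest other split, and 0 rows between the drugs and 0 label-checked genes in each comparison by edgeR, as in all 10 splits. By DESeq2 the real labels gave 84 rows between the drugs and 29, 3 and 8 label-checked genes, and at an unadjusted p under 0.05 edgeR gave 1173 rows and 119, 41 and 54 label-checked genes.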
